A study of Homo sapiens with 4 samples.

How the data were processed

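Polyadenylated RNA was sequenced from 2 libraries of the human breast cancer cell line Cal51 and 2 of its doxorubicin-resistant derivative Cal51R. Per the labels' protocols, mRNA was enriched with oligo(dT) beads, fragmented, converted to cDNA, amplified by PCR, circularised and sequenced as DNA nanoballs. Molecular identifiers and strand-specific counting are not given in the sources used here, so reads of overlapping antisense genes cannot be told apart, and intervals and detection limits cover counting error only.

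The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.5, RSEM 1.2.8, DESeq and the human genome build hg38, without saying which step each served. The gene annotation is not given in the sources used here. One deposited table covered 17215 genes, almost all protein coding (17090 by the RefSeq table). Per the file headers it gives, for each library, the authors' read counts, FPKM and TPM, and their mean for each line. Per the file headers, the authors deposited read counts per gene, and from their values these are expected counts that need not be whole. Of the values, which the file gives to 2 decimals, 27.0% to 31.8% in each library were exactly whole, zeros included, and the totals of 17852484 to 21637102 differ between libraries, as those of unscaled counts do. The authors' TPM columns each sum to 1000000. The FPKM values deposited by the authors were used only in alternatives, and the TPM values and the authors' means were not used in any test. Libraries were assigned to columns by their titles, and no column was left over.

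Expected counts were rounded to whole numbers, which are the reads given for single genes. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, the filterByExpr filter (minimum count 10), and the line as the only term in the model. It tested 13674 genes and left out 3541. Fold changes are Cal51R over Cal51, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are said to have risen or fallen. SE is the log2 fold change divided by the root of the test's F value. The typical spread between replicates, as a coefficient of variation, was 5.83%. CPM values are counts divided by the TMM-scaled library size. The TMM factors were 0.939 and 0.927 for Cal51 and 1.06 and 1.09 for Cal51R, so that scaling by totals alone moves the median fold change by 0.20 (log2).

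Before the data were examined, 33 gene lists were fixed for drug transport and metabolism, stress responses, cell cycle, repair, apoptosis, inflammation, metabolism, cell shape and markers of other cell types, together with the tests, the alternatives and the rule for naming genes. The rule names the 3 genes of the series title. It then takes 12 genes in each direction with the largest fitted fold change, a mean over all 4 libraries of at least 10 CPM and no overlap between the lines, so that a gene seen in 1 line only needs a higher level there. From each list it takes up to 2 genes that rose and 2 that fell with the smallest p, from the deubiquitinases up to 5 each way by fold change with a mean over all 4 libraries of at least 1 CPM, and from marker lists also the most abundant member. Some genes that the rule takes are not reported here. Lists with at least 5 tested members, 30 in all, were tested on log2 CPM (prior count 2) with limma 3.58.1's camera at a preset correlation of 0.01, and also with an estimated correlation and with fry, each adjusted over lists. Where a line had no read of a gene, the fold change is given as a bound against 3 counts per library. Where it had 1 to 3 reads, it is given as a ratio with an exact 95% interval. With genes at their bound, 0 of the 30 list medians differed.

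Gene positions come from a RefSeq table for GRCh38.p14, the assembly named hg38 in the notes, matched on gene ID for 99.7% of the genes. They are the span of each gene. GC content and transcript length came from GENCODE protein-coding transcripts, the median per gene, for 98.5% of the genes. Alternatives were DESeq2 1.42.0, RLE factors, library totals, no filter, a filter of 5 CPM in 2 libraries, totals without the 10 highest genes, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, and leaving out each library. The FPKM alternatives kept genes with at least 1 FPKM in 2 libraries, and depend on a pseudocount that understates the change of low genes. The test functions were tested on simulated data with 200 changed genes drawn at the spread of these libraries. Of 50 genes each changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, edgeR recovered 32%, 66%, 82% and 98%, with 8 false calls among 13566 genes tested. A simulated list of 30 genes raised 1.5-fold was called by camera, and 0 of 29 random lists were. The simulated genes varied independently and few of them changed, whereas 70.8% of tested genes passed in the real data. The simulation thus checks that the functions work, and its rates need not hold for these data. It cannot show whether the preset correlation calls too many lists of genes that vary together.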

Results

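RNA sequencing was used to compare Cal51, a triple-negative breast cancer cell line, with Cal51R, a line derived from it that is resistant to doxorubicin, an anthracycline that poisons topoisomerase II. Each line was represented by 2 libraries, and the purpose stated for the comparison was to find deubiquitinases, enzymes that remove ubiquitin from proteins, that are tied to resistance. The libraries held 21637102 and 18537823 estimated read counts for Cal51 and 17852484 and 19854907 for Cal51R, over 17215 genes. A count of 3 reads, taken as the limit of detection, amounted to 0.139 to 0.174 counts per 1000000 (CPM). Nothing in the sample labels says whether the 2 libraries of a line came from separate cultures, so p-values of single genes measure the spread between these libraries, which may be technical. Camera p-values compare the genes of a list with the other genes tested, and are not a measure of that spread. The log2 CPM of the libraries of one line correlated across genes with r = 0.994 (Cal51) and r = 0.994 (Cal51R), and those of libraries from different lines with r = 0.869 to 0.875, where genes are not independent replicates. Replicates of a line differed by more than counting noise, with a chi-square per gene of 4.50 for Cal51 and 6.91 for Cal51R.

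The 2 lines differed in most of their expressed genes. Of 13674 genes tested, 9685 (70.8%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4830 of them higher and 4855 lower in Cal51R, and the median absolute log2 fold change was 0.50. At least 2-fold, 1878 genes rose and 1350 fell. The split by direction depended on scaling. With library totals in place of TMM factors the median gene's fold change shifted by 0.20 (log2) and 64.7% of the genes that passed were higher, against 49.9%, and on log2(FPKM + 1) 63.7% were higher, with a shift of 0.19. Fold changes below are relative to TMM scaling. The 119 genes taken by the naming rule that passed with a fitted fold change had SEs of 0.07 to 0.37 (log2, median 0.09) and adjusted p-values of at most 0.0421.

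Several genes were near the limit of detection in one line and abundant in the other. Among the 12 genes with the largest increase at a mean of at least 10 CPM over all 4 libraries, BMPR1B, a receptor for bone morphogenetic proteins, had 1 read over both Cal51 libraries and 56.7 ± 3.11 CPM in Cal51R (mean ± SD, n = 2, as for all CPM values below), a ratio of 2134 with a 95% counting interval of 382.7 to 84330. POU3F3, a POU-domain transcription factor, went from 0.152 ± 0.133 to 268.6 ± 5.70 CPM. GPX1, a glutathione peroxidase, went from 0.152 ± 0.133 to 142.5 ± 23.2 CPM. The chemokine gene CCL20 rose from 4.00 ± 0.0562 to 534.2 ± 6.46 CPM, a log2 fold change of 7.06 ± 0.11 (SE). WNT5A, which encodes a secreted Wnt ligand, rose from 0.711 ± 0.310 to 71.7 ± 8.00 CPM, and PLCB4, a phospholipase C gene, from 0.676 ± 0.297 to 70.7 ± 7.85 CPM. NPNT, MYO18B and MTTP had 2, 2 and 3 reads over both Cal51 libraries and reached 30.5, 26.4 and 34.4 CPM, with ratios of 575 (interval 159 to 4756), 495 (137 to 4093) and 431 (147 to 2093). ME3, SH3RF3 and DAB1 rose from 0.136, 0.293 and 0.957 CPM to 33.2, 35.6 and 99.4 CPM.

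Among the 12 genes with the largest decrease under the same limit, 5 genes at 31.6 to 51.8 CPM in Cal51 had no read in either Cal51R library. Against the level of 3 counts per library, MGMT was at least 227-fold lower, GPC3 at least 347-fold, BMP5 at least 231-fold, AEBP1 at least 220-fold and SULF1 at least 212-fold. MGMT encodes the enzyme that repairs O6-methylguanine in DNA, and GPC3 a glypican of the cell surface. SLC2A3, the gene of the glucose transporter GLUT3 (chromosome 12, 7919230 to 7936187), had 18307 reads in Cal51 and 1 in Cal51R, a ratio of 19730 with a 95% counting interval of 3541 to 779300. Reads can be split between SLC2A3 and its near-identical copy SLC2A14, which held 11 reads in 1 Cal51 library and 0 in the others. DSC3, a desmosomal cadherin, and SPP1, osteopontin, fell from 283.5 and 274.7 CPM to 0.106 and 0.0961 CPM. ITM2A, ADGRG6, TUB and THSD7A, at 205.0, 154.5, 55.8 and 54.0 CPM in Cal51, had 2, 2, 1 and 2 reads in Cal51R, with ratios of 4147 (interval 1148 to 34250), 3139 (868.7 to 25930), 2262 (405.6 to 89390) and 1096 (303 to 9056).

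The series names 3 genes. They are the deubiquitinase USP51, the endoplasmic reticulum chaperone GRP78, encoded by HSPA5, and the drug efflux pump P-glycoprotein, encoded by ABCB1. The values here are RNA levels and do not measure the amount or activity of these proteins. USP51 (gene 158880, GRCh38 chromosome X, 55484616 to 55489848) rose 2.93-fold, from 1.35 ± 0.386 to 3.92 ± 0.225 CPM, a log2 fold change of 1.55 ± 0.26 (SE; edgeR adjusted p = 6.5e-05). It was a low transcript, with 22 and 28 reads in the Cal51 libraries and 71 and 88 in Cal51R. Of the tested genes within 1 Mb of USP51, those at higher coordinates, RRAGB and KLF8, rose by 1.72 and 2.42 (log2). At lower coordinates MAGED2 rose by 0.584, and FGD1, GNL3L and APEX2 had log2 fold changes of -0.241, -0.304 and -0.899. FAM104B and MTRNR2L10, also at lower coordinates, did not pass. Whether USP51 rose as part of a segment was not tested. HSPA5 (gene 3309, chromosome 9, 125234853 to 125241343) was abundant in both lines, at 1634 ± 44.2 CPM in Cal51 and 1677 ± 8.22 CPM in Cal51R. Its log2 fold change of 0.04 ± 0.07 (SE) did not pass (edgeR adjusted p = 0.667), and its 95% interval excluded changes beyond 0.92-fold and 1.14-fold. This call depended on scaling. HSPA5 passed with library totals, higher by 0.24 (log2; edgeR adjusted p = 0.00452), of which 0.20 was the shift of the median gene, and on log2(FPKM + 1), higher by 0.24 (limma adjusted p = 0.0237; 0.00452 to 0.998 over the 14 alternatives).

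ABCB1 (gene 5243, chromosome 7, 87503017 to 87713295) was not detected above the limit in any library. It had 0 and 0 reads in Cal51 and 0 and 2 in Cal51R, and at this depth a level under 0.174 CPM would not have been seen. ABCB1 had too few reads for the filter and was left out of the test. Tested with no filter on low counts, it did not pass (edgeR adjusted p = 0.356).

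**Figure D1:**
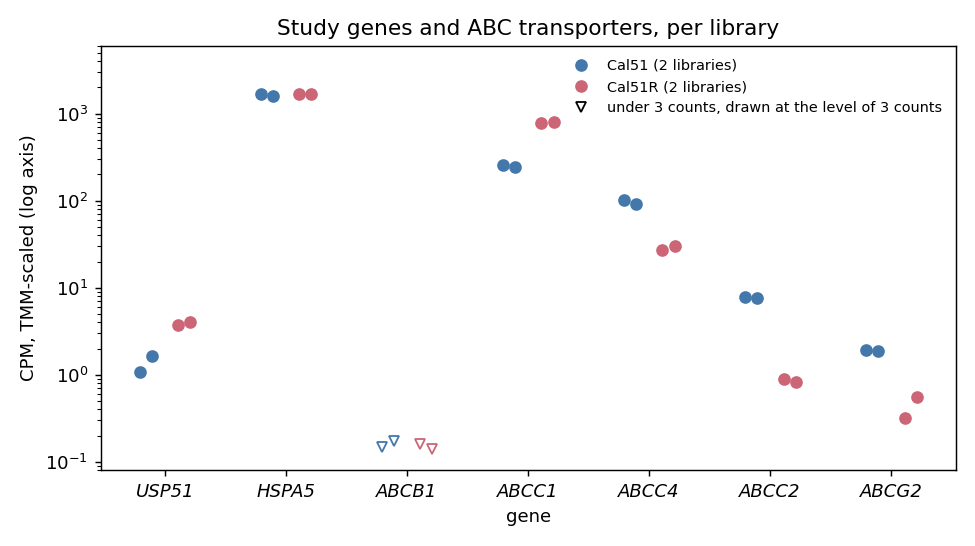
Each point is 1 library's TMM-scaled CPM on a log axis for USP51, HSPA5, ABCB1 and 4 other ABC transporter genes, in Cal51 (blue) and Cal51R (red); open triangles mark libraries under 3 counts, drawn at the CPM of 3 counts. ABCB1 lies under the limit in all 4 libraries, HSPA5 lies between 1603 and 1683 CPM in all 4, and ABCC1 lies near 249 CPM in Cal51 and 790 CPM in Cal51R.

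For the deubiquitinases, the class the study searched, 60 of 88 tested genes changed: 36 rose, 24 fell and 28 did not pass (59 of 88 adjusted over the list alone). Over all genes tested 70.8% passed, so a count of this size is not particular to deubiquitinases. At least 2-fold, 7 rose and 5 fell. TNFAIP3, which encodes the NF-kB regulator A20, rose most, from 37.9 ± 0.557 to 176.0 ± 6.84 CPM (log2 fold change 2.21 ± 0.08, SE). MINDY1 rose 3.48-fold, OTUB2 3.07-fold, and CYLD, a tumour suppressor that restrains NF-kB signalling, rose from 30.9 ± 0.853 to 68.0 ± 5.17 CPM. Among the deubiquitinases that rose, TNFAIP3, MINDY1 and OTUB2 had larger fold changes than USP51. USP44, a regulator of the mitotic checkpoint, was lowest: 75.1 ± 1.88 CPM in Cal51 and 0.368 ± 0.0703 CPM in Cal51R (log2 fold change -7.64 ± 0.17, SE). USP2 fell 5.29-fold, UCHL3 2.74-fold, USP1, which deubiquitinates PCNA and FANCD2, 2.41-fold, and USP4 2.01-fold. As a list the deubiquitinases did not shift against other genes (limma camera adjusted p = 0.454, median log2 fold change 0.17).

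**Figure D2:**
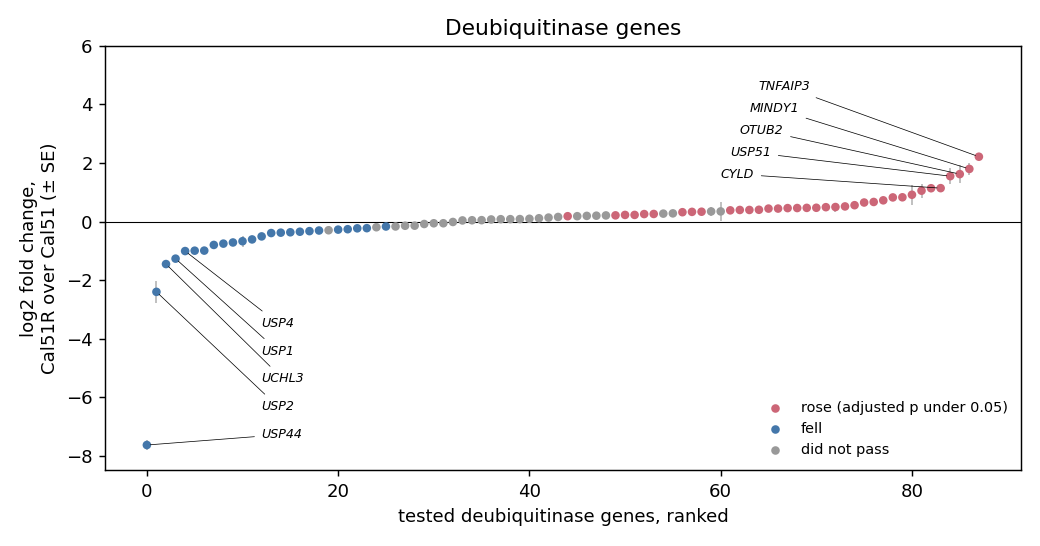
Log2 fold change, Cal51R over Cal51, of the 88 tested deubiquitinase genes ranked from lowest to highest, with bars of ± SE and colours for genes that rose, fell or did not pass an adjusted p of 0.05. USP44 stands apart at -7.64 and TNFAIP3 is highest at 2.21.

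ABC transporter genes moved in both directions: of 33 tested, 16 rose, 9 fell and 8 did not pass (camera adjusted p = 0.373; 25 passed adjusted over the list alone). The lipid transporter genes ABCA3 and ABCA1 rose 11.7-fold and 10.4-fold. ABCC1, the drug efflux pump MRP1 and a known carrier of doxorubicin (chromosome 16, 15949143 to 16143053), rose 3.17-fold, from 249.0 ± 6.87 to 789.7 ± 15.4 CPM (log2 fold change 1.66 ± 0.07, SE; edgeR adjusted p = 6.77e-12). ABCC2 fell 8.83-fold and ABCC4 3.36-fold. ABCG2, the breast cancer resistance protein, was looked up after its values were seen and fell from 1.89 ± 0.0408 to 0.437 ± 0.169 CPM. Of 23 tested genes that flank ABCB1 on 7q21, 10 rose and 7 fell (17 adjusted over the list alone; camera adjusted p = 0.425). CROT rose 2.89-fold and ANKIB1 1.74-fold, while TMEM243 fell 1.70-fold and DBF4 1.54-fold.

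Among 13 tested carbonyl and quinone reductase genes that can act on anthracyclines, 4 rose and 4 fell (8 adjusted over the list alone; camera adjusted p = 0.775). AKR1C2 rose 2.90-fold, though its reads can be shared with the near-identical AKR1C1, and AKR1A1 rose 1.74-fold. NQO1, a quinone reductase, fell 2.73-fold, and POR, the reductase of cytochrome P450 enzymes, fell from 184.0 ± 0.414 to 87.7 ± 11.7 CPM. Of 27 NRF2 target genes, 14 rose and 9 fell (23 adjusted over the list alone; camera adjusted p = 0.560), with SLC7A11, the cystine transporter, up 6.61-fold and TXN, thioredoxin, down 3.42-fold. Of 16 glutathione transferase genes, 4 rose and 7 fell (11 adjusted over the list alone; camera adjusted p = 0.581). GSTP1 rose 1.90-fold and GSTO2 1.96-fold. GSTM2, one of a set of similar genes, fell from 41.0 ± 0.290 to 1.34 ± 0.398 CPM, and MGST1 fell 2.00-fold.

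The gene lists that rose were interferon-stimulated genes, NF-kB and inflammatory genes, and the integrated stress response. All 3 were called by camera with a preset correlation. None of the 30 lists tested was called with an estimated correlation, where 2 had an unadjusted p under 0.05. By fry, which asks whether a list's own genes move on balance one way, 21 lists passed, and all 30 passed its test for change in either direction. Of 37 interferon-stimulated genes, 28 rose and 5 fell (33 adjusted over the list alone), with a median log2 fold change of 1.90 (camera adjusted p = 1.41e-06; adjusted p = 0.533 with an estimated correlation). IFIT2, an antiviral RNA-binding protein, rose from 18.0 ± 0.743 to 163.6 ± 15.6 CPM and RSAD2, viperin, from 0.944 ± 0.266 to 32.1 ± 1.41 CPM. EPSTI1 fell 4.64-fold and IFITM2, which has close copies, 2.48-fold.

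Of 23 NF-kB and inflammatory genes, 19 rose and 3 fell (22 adjusted over the list alone), with a median log2 fold change of 1.37 (camera adjusted p = 2.23e-05; adjusted p = 0.533 with an estimated correlation). Besides CCL20, the neutrophil chemokine gene CXCL5 rose from 142.9 ± 8.42 to 1414 ± 78.1 CPM. IL1B fell 3.41-fold and IER3 1.93-fold. All 25 integrated stress response genes changed, with 22 higher and 3 lower (25 adjusted over the list alone), and the median was 0.75 (camera adjusted p = 0.000143; adjusted p = 0.662 with an estimated correlation). SLC7A11 and ASNS, asparagine synthetase, rose 6.61-fold and 4.36-fold, while the amino acid transporter gene SLC7A5 fell 2.82-fold and VLDLR 1.42-fold. Of 15 genes of MHC class I presentation, 10 rose and 1 fell (11 adjusted over the list alone; camera adjusted p = 0.0534; adjusted p = 0.662 with an estimated correlation). ERAP2 and ERAP1, which trim antigenic peptides, rose 5.21-fold and 1.81-fold. NLRC5, the transactivator of class I genes, fell 1.68-fold.

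Glycolysis, hypoxia targets, DNA replication and proteasome subunits were the lists that fell. No glycolysis gene rose: 20 of 21 fell (20 adjusted over the list alone), with a median log2 fold change of -0.83 (camera adjusted p = 2.68e-06; adjusted p = 0.662 with an estimated correlation). SLC2A1, the glucose transporter GLUT1, fell from 1155 ± 21.7 to 100.6 ± 6.76 CPM, beside the loss of SLC2A3. Of 23 hypoxia targets, 16 fell and 5 rose (21 adjusted over the list alone), with a median of -0.70 (camera adjusted p = 0.00652; adjusted p = 0.662 with an estimated correlation). The hypoxia median was -1.07 without Cal51 replicate 2 and -0.40 on log2(FPKM + 1), and the list was called in both (camera adjusted p = 0.00103 and 0.000627; 0.000627 to 0.0108 over the alternatives). This list shares SLC2A1 with glycolysis. ADM, the vasodilator peptide adrenomedullin, fell 18.1-fold, whereas NDRG1 rose 4.95-fold and VEGFA 1.35-fold.

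Of 32 DNA replication genes, 28 fell and 1 rose (29 adjusted over the list alone), with a median of -0.77 (camera adjusted p = 2.42e-06; adjusted p = 0.662 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, fell from 362.9 ± 5.04 to 121.4 ± 5.59 CPM and UHRF1, which maintains DNA methylation, from 171.1 ± 1.05 to 61.8 ± 0.934 CPM. RFC1, a clamp loader subunit, rose 1.73-fold. Of 30 mitotic genes, 15 fell and 5 rose (20 adjusted over the list alone; camera adjusted p = 0.117). MAD2L1 and TOP2A fell 2.51-fold and 2.35-fold, and CENPE rose 1.85-fold. BIRC5 rose 1.19-fold, a call lost without Cal51 replicate 1 (log2 fold change 0.17; edgeR adjusted p = 0.219; 1.3e-06 to 0.219 over the alternatives). Of 32 proteasome genes, 23 fell and 4 rose (28 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 0.0124; adjusted p = 0.828 with an estimated correlation; by fry, which the other 6 called lists passed, adjusted p = 0.0667). PSMC2 fell 1.87-fold, PSMD13 fell from 158.9 ± 15.1 to 105.9 ± 7.40 CPM, and PSMB6 rose 1.38-fold and PSMC5 1.23-fold. The proteasome median was -0.15 with library totals (camera adjusted p = 0.0411), 0.428 of its size, and the call was lost on log2(FPKM + 1) and log2(FPKM + 0.1) (camera adjusted p = 0.0954 and 0.0706; 0.00403 to 0.0954 over the alternatives). PSMC5 did not pass without Cal51 replicate 1 (edgeR adjusted p = 0.106; 6.67e-08 to 0.106 over the alternatives).

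**Figure D3:**
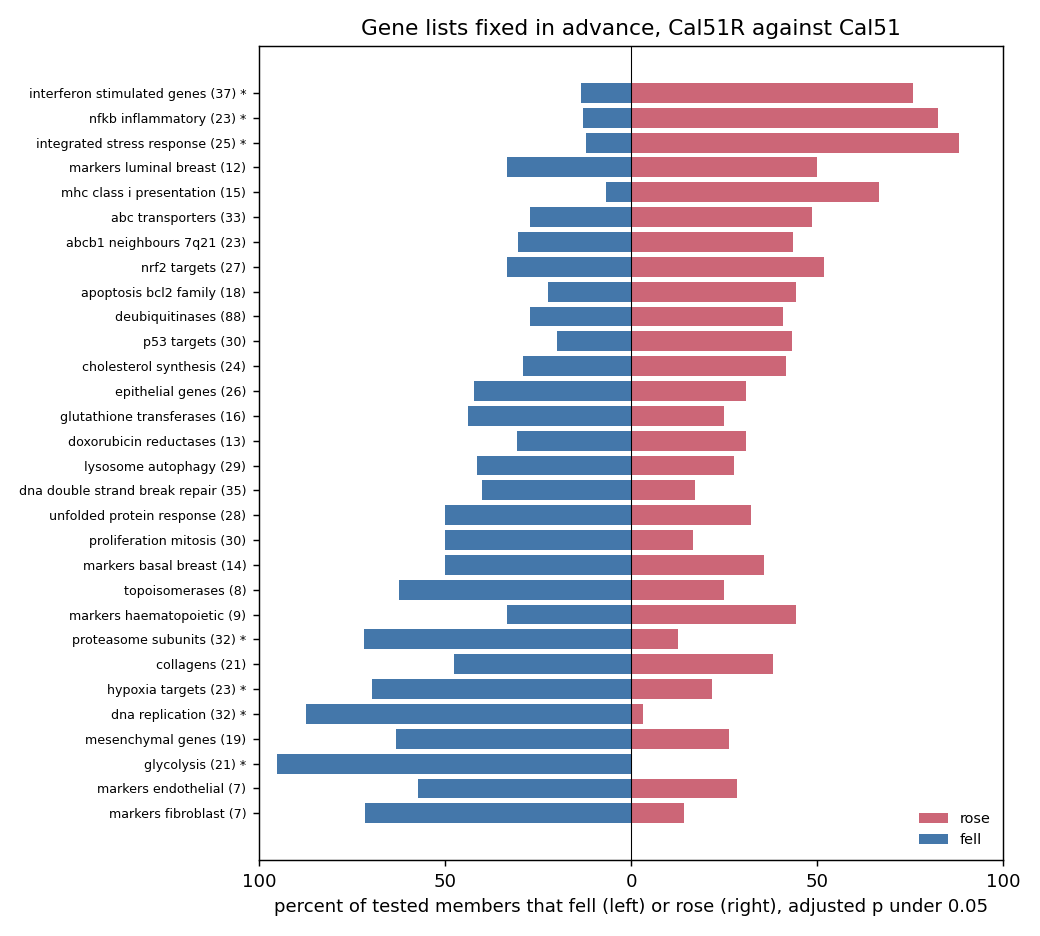
For the 30 gene lists with at least 5 tested members (number tested in brackets), bars give the percent of tested members that fell (left, blue) or rose (right, red) in Cal51R at an adjusted p under 0.05, ordered by median log2 fold change; an asterisk marks lists called by camera with a preset correlation. Interferon-stimulated genes are at the top with 28 of 37 higher, and 20 of 21 glycolysis genes fell.

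Topoisomerase and damage-response genes were mixed. TOP2A, a topoisomerase II gene, fell from 398.2 ± 18.9 to 169.6 ± 13.6 CPM (log2 fold change -1.23 ± 0.08, SE, edgeR adjusted p = 7.61e-10). The other topoisomerase II gene, TOP2B, was not taken by the naming rule. At 248.8 ± 2.04 CPM in Cal51 and 234.5 ± 13.4 CPM in Cal51R, TOP2B did not pass (edgeR adjusted p = 0.308). TOP1 fell 1.53-fold. Of 8 topoisomerase and related genes, 5 fell and 2 rose (7 adjusted over the list alone; camera adjusted p = 0.337). TOP3B and TDP2 rose 1.22-fold and 1.15-fold, and neither passed with DESeq2 (adjusted p = 0.141 and 0.185), without Cal51 replicate 1 (edgeR adjusted p = 0.127 and 0.258) or without Cal51 replicate 2 (0.104 and 0.222). TDP2 did not pass without Cal51R replicate 2, with no filter or with RLE factors either (edgeR adjusted p = 0.0796, 0.0795 and 0.0523), and the adjusted p over all alternatives ran from 0.000327 to 0.141 for TOP3B and from 0.000238 to 0.258 for TDP2. Of 30 p53 targets, 13 rose and 6 fell (19 adjusted over the list alone; camera adjusted p = 0.382). EDA2R, a receptor of the TNF receptor family, rose 25.2-fold and PMAIP1, the BH3-only protein NOXA, 2.13-fold. BAX, an effector of mitochondrial apoptosis, fell from 218.5 ± 16.4 to 42.0 ± 3.54 CPM, and CCNG1 fell 1.63-fold. Of 18 BCL2 family genes, 8 rose and 4 fell (12 adjusted over the list alone; camera adjusted p = 0.370). BMF rose 4.83-fold and BCL2L11, which encodes BIM, fell 2.48-fold. Of 35 double-strand break repair genes, 6 rose and 14 fell (20 adjusted over the list alone; camera adjusted p = 0.337). ATM, the kinase that signals breaks, rose 2.07-fold and TP53BP1 1.45-fold, while XRCC3 and EXO1 fell 1.86-fold each. In the unfolded protein response, the pathway of HSPA5, 14 of 28 genes fell and 9 rose (23 adjusted over the list alone; camera adjusted p = 0.642). SEC24D and XBP1 rose 2.16-fold and 1.60-fold, and HERPUD1 and PDIA4 fell 2.06-fold and 1.60-fold.

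Genes of cell shape and matrix changed strongly in both directions. Of 26 epithelial genes, 8 rose and 11 fell (19 adjusted over the list alone; camera adjusted p = 0.642), among them KRT19, up 23.4-fold, ELF3, up 2.94-fold, the desmosomal gene DSP, down 6.65-fold, and SPINT2, down 3.57-fold. Of 19 mesenchymal genes, 5 rose and 12 fell, with a median of -0.79 (17 adjusted over the list alone; camera adjusted p = 0.0752). SPARC, a matrix glycoprotein, fell from 1015 ± 13.7 to 6.19 ± 0.955 CPM and PDGFRB, a growth factor receptor, from 69.0 ± 3.58 to 0.513 ± 0.126 CPM. FN1, fibronectin, rose by 2.51 ± 0.09 (log2, SE), from 242.6 to 1380 CPM, and FBN1 3.85-fold. Of 21 collagens, 8 rose and 10 fell (19 adjusted over the list alone; camera adjusted p = 0.642), with COL4A5 up 8.81-fold, COL12A1 up 3.12-fold, COL5A2 down 55.8-fold and COL1A2 down 4.09-fold.

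Markers of other cell types were measured beside these. Of 7 tested fibroblast markers, which include PDGFRB and COL1A2, 5 fell and 1 rose (6 adjusted over the list alone; camera adjusted p = 0.0589). PDGFRA, at 1.78 ± 0.361 and 3.08 ± 0.164 CPM, was the one that rose, a call lost with DESeq2 (adjusted p = 0.131) and without Cal51 replicate 1 (edgeR adjusted p = 0.129; 0.00184 to 0.131 over the alternatives). Of 7 endothelial markers, 2 rose and 4 fell (6 adjusted over the list alone; camera adjusted p = 0.382). PECAM1 was the most abundant, at 50.6 ± 2.85 and 134.5 ± 5.09 CPM. CDH5 rose 16.4-fold, TEK fell 7.46-fold and EGFL7 1.99-fold. Of 9 haematopoietic markers, 4 rose and 3 fell (7 adjusted over the list alone; camera adjusted p = 0.880). The most abundant, CORO1A, was at 19.0 ± 1.94 and 12.2 ± 1.53 CPM. CD74 and CD79B rose 3.24-fold and 3.84-fold, CD68 fell 6.65-fold, and CD14 had 104 reads in Cal51 and 2 in Cal51R, a ratio of 56.0 (95% counting interval 15.1 to 468.9). The haematopoietic list's median (-0.30) and mean (-0.32) lay below 0 while its camera direction was up.

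Of 12 luminal breast markers, 6 rose and 4 fell (11 adjusted over the list alone; camera adjusted p = 0.519). KRT8 and KRT18, the keratins of simple epithelia, were at 7859 and 5395 CPM in Cal51 and fell 2.16-fold and 2.08-fold. Of 14 basal markers, 5 rose and 7 fell (12 adjusted over the list alone; camera adjusted p = 0.642). The laminin gene LAMB3 rose 3.68-fold. ITGB4 and CDH3 fell 3.43-fold and 2.86-fold.

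Other lists did not pass camera either. Of 24 cholesterol synthesis genes, 10 rose and 7 fell (17 adjusted over the list alone; camera adjusted p = 0.880). The median of the cholesterol list was -0.01 (log2) and its mean 0.03, and the camera direction was up. INSIG1 rose 1.76-fold and LSS 1.56-fold. STARD4 fell 1.52-fold (log2 fold change -0.61). On log2(FPKM + 1) and log2(FPKM + 0.1) its log2 fold change shrank to -0.17 and -0.18 and the call was lost (limma adjusted p = 0.164 and 0.17, and 8.21e-18 to 0.17 over the alternatives). Of 29 lysosome and autophagy genes, 8 rose and 12 fell (20 adjusted over the list alone; camera adjusted p = 0.581). GAA rose 3.54-fold and ULK1 1.81-fold, and LAMP1 fell 3.15-fold and GABARAPL1 1.95-fold. Of the cancer-testis genes only CT45A1, one of several near-identical copies, had enough reads to test. It had 0 reads in Cal51 and 69 in Cal51R, at least 10.9-fold higher. Mitochondrially encoded genes were not analysed here.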

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

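The crossed pairing was added after the data were seen. No gene taken by the naming rule with a fitted value reversed: over 137 genes and 1899 gene-by-setting values, 1879 kept direction and call, 17 lost the call and 3 gained it, all 3 for HSPA5. HSPA5 passed with library totals (log2 fold change 0.236), log2(FPKM + 1) (0.2359) and log2(FPKM + 0.1) (0.2364), where the scaling shift of 0.199, 0.188 and 0.196 was nearly the whole change; it ranged from 0.00039 to 0.236 over 14 settings. USP51 passed in the 11 settings that tested it (log2 1.26 to 1.84, adjusted p up to 0.00146); the filter of 5 CPM and the FPKM settings left it out, and ABCB1 had an adjusted p only with no filter. DESeq2 was not used for list tests, and leaving out a library assumes that the lone one varies like the other line's. DESeq2 called 8247 genes, 8156 of them shared with edgeR in the same direction. On log2(FPKM + 1) and log2(FPKM + 0.1), 3216 and 3201 genes were lower in place of 4855, and 666 and 797 lower at least 2-fold in place of 1350; on log2(FPKM + 1), 1173 were higher at least 2-fold and 1839 changed at least 2-fold, in place of 1878 and 3228. The filter of 5 CPM, which tests 11424 genes, left 2131 changed at least 2-fold and 1230 higher. The 7 lists called by camera became 0 with an estimated correlation; fry called 21, among them 6 of the 7 but not proteasome subunits. Lists that camera called in no setting changed its direction in some. For cholesterol synthesis the median was -0.0298 without a filter, -0.0147 under the crossed block and -0.0513 to 0.0183 when libraries were left out; doxorubicin reductases gave -0.134 to 0.0559 when libraries were left out. Haematopoietic markers gave -0.31 (crossed block), -0.104 (library totals), -0.442 and -0.405 (FPKM + 0.1 and + 1), -0.566 (no filter), -0.355 (replicate block) and -0.415 to 0.115 when libraries were left out. Luminal markers gave 0.566 and 0.558 on FPKM + 0.1 and + 1. The causes were not tested. The medians of 10 lists that were not called changed sign in at least 1 setting. MHC class I presentation, mesenchymal and fibroblast lists passed in 6, 5 and 6 of 13 settings. The replicate differences of the lines correlated negatively (r = -0.16), so libraries of the same number did not differ in the same direction. With the replicate block 8905 genes passed. With the crossed pairing, which joins Cal51 replicate 1 to Cal51R replicate 2, 10657 passed. That gain goes with the sign of r and does not by itself show a pairing. What libraries of different number share was not tested. Of the genes taken by the naming rule, TOP3B and TDP2 did not pass with the replicate block (edgeR adjusted p = 0.0504 and 0.141), and it changed no other call among them. Depth limits genes near 0.174 CPM, such as ABCB1.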

Other observations

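The gene families and chromosome windows in this and the next paragraph were chosen after the data were seen. Of 26 tested genes of the clustered protocadherins, adhesion proteins of the 5q31 arrays, 21 rose and 2 fell in Cal51R, with a median log2 fold change of 2.68. Members of the alpha array share their last exons, as do those of the gamma array, so reads there cannot be assigned to single members with certainty. Of 467 tested ZNF zinc finger genes, 305 rose and 41 fell (median 0.51, or 0.70 with library totals). Ribosomal protein genes went the other way, with 55 of 79 lower and 3 higher, by a median of -0.26 that shrank to -0.06 with library totals. Of 29 tested HOX genes, 16 rose and 5 fell. The HOXA genes HOXA9 (132 and 132 CPM), HOXA5 (32.6 and 32.5 CPM) and HOXA13 (14.3 and 13.3 CPM) did not pass with TMM scaling, while HOXB6 (0.597 to 7.08 CPM) and HOXA7 (3.09 to 34.5 CPM) rose and HOXC10 (4.13 to 0.291 CPM) fell.

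Fold changes also ran together along chromosomes. Chromosome 13 had the lowest median of all chromosomes, -0.43, with 120 of 218 tested genes lower and 51 higher. In windows of 25 consecutive tested genes, all 25 fell between RBM26 and TMTC4 on chromosome 13 (79311827 to 100675075), the segment that holds ABCC4, with a median of -1.34. A window at the end of the same chromosome (108218392 to 114272723) had a median of -1.21, and windows on chromosome 9 (104764129 to 111935369) and chromosome 7 (130070534 to 135977359) had -1.25 and -1.14. The lowest window median in 1000 shuffles of the gene order was -0.917. On the high side, the protocadherin arrays (2.74) exceeded the highest shuffled window (1.37), while the window on chromosome 16 that holds ABCC1 (11976734 to 16393972) had a median of 1.22 and did not. These bounds are the most extreme windows over all 1000 shuffles, so falling short of one does not show that a window is ordinary. The shuffles treat genes as independent, which protocadherin members with shared last exons are not. The excess of their window thus does not by itself show a regional change.

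The first pattern weighed is the rise of ABCC1 with ABCB1 under the limit of detection; the tests of depth and of ABCB4 reads were chosen after their values were seen, the test of neighbouring genes before. Depth argues against a missed ABCB1 level of 1 CPM, since 3 counts amount to at most 0.174 CPM, and its near relative ABCB4 reached at most 0.649 CPM, so that ABCB1 reads amounting to 1 CPM were not counted there. Of 13 tested genes within 1 Mb of ABCC1, not counting ABCC6, which was left out beforehand and also rose (log2 fold change 1.51), 11 rose and 1 fell, with a median log2 fold change of 1.64, above 99.8% of windows of as many consecutive genes; without the NPIPA and NOMO copies the median of the other 9 was also 1.64. The values of the 13 genes ran from -0.22 (NTAN1) to 3.63 (NOMO3). The wider window of 25 genes, at 1.22, lay below the highest window of all shuffles (1.37), which does not say how rare such a median is. As a hypothesis, Cal51R may carry extra copies of this part of chromosome 16, which DNA would have to show.

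The second pattern is the set of genes abundant in one line and at or near 0 in the other: 23 genes had at least 10 CPM in both Cal51 libraries and at most 3 reads in Cal51R, and 10 the reverse, among them CES1 (0 reads against 679) and CD200 (0 against 455). The count of the reverse set was the test chosen after the result was seen, with its bound at the 10 already counted, so it decides nothing. A wider limit, a mean under 1 CPM in the other line in place of at most 3 reads, gave 79 genes and 58 the reverse, among them POU3F3 and GPX1. Loss of segments in Cal51R is weighed for the 23 alone, since the 10 have reads in that line. For the 23, both nearest neighbours that Cal51 expresses, other lost genes included, were still at 1 CPM or more in 69.6%. For other genes at 10 CPM or more in both Cal51 libraries the share was 93.1%. Of the 23, 7 kept 1 of these neighbours and 0 lost both. With lost genes passed over, as the prediction was worded but not first run, the share of the 23 was 78.3%. No comparison with other genes was made in that form. Both shares of the 23 lie between the values set for and against loss of segments, so loss of single segments and silencing stay open. The HOX genes at 1 CPM or more overlapped with a Jaccard index of 0.552 (16 of 29), also between its set bounds. The index depends on the cut. Some genes crossed 1 CPM narrowly, such as HOXD3 (1.53 and 0.954 CPM) and HOXC9 (0.606 and 1.33 CPM). Others crossed it by more. HOXB3, HOXB5, HOXB6, HOXB8 and HOXB9 went from 0, 0.0537, 0.597, 0.116 and 0.403 CPM in Cal51 to 2.48, 2.37, 7.08, 1.83 and 5.49 CPM in Cal51R. HOXC6, HOXC10, HOXC11 and HOXC13 went from 1.2, 4.13, 1.68 and 5.51 CPM to 0.344, 0.291, 0.126 and 0.808 CPM. HOXA2 and HOXA4 also crossed upward, from 0.928 and 0.66 CPM to 6.16 and 1.69 CPM. By this index a culture of different origin cannot be told apart from a derived line, and genotypes would decide it.

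The third pattern is the fall of the glycolysis, hypoxia and replication lists with the rise of the interferon and NF-kB lists, for which both tests were set before their results were seen. After a trend of fold change on GC content and transcript length was removed, each of the 5 lists kept at least 0.947 of its median. Such a trend is thus not the whole cause for these 5. Over all genes the fold change correlated weakly with GC content (Spearman -0.0098) and log2 length (0.087). With library totals each list kept at least 0.717. That share follows from a shift of 0.20 set against medians of at least 0.70 in size. It shows only that the choice between TMM factors and totals is not the whole cause for these 5. Of the 2 other called lists, which are not part of the pattern, the integrated stress response kept 0.927 and 1.27 of its median and the proteasome list 0.894 and 0.428, so scaling stays open as a cause of the proteasome fall. Culture density, oxygen and medium were not tested and stay open beside resistance itself, as they would differ between the lines in the same way.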
